A study of Caenorhabditis elegans with 4 samples.

How the data were processed

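ChIP-seq of GFP-tagged DPL-1 was performed on fed L1 larvae grown at 20 °C on bacteria and fixed with 2% formaldehyde, per the labels' protocols. There were 4 samples, with 2 anti-GFP ChIP libraries and 2 input libraries that share replicate numbers 1 and 2. The peak lists of the ChIP libraries were used, together with 1 list of both ChIP replicates combined, and samples were grouped by their titles.

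The authors deposited the peaks as intervals on WormBase build WS220, per the file headers. The method column of each file names SPP, a peak caller for ChIP-seq, and IDR, the irreproducible discovery rate used to compare replicate peak lists. The aligner, read filters, thresholds and the use made of the input libraries are not given in the sources used here. Peaks were deposited per replicate and for both replicates combined. How the combined list was selected is not given in the sources used here. Each peak carries a score as deposited by the authors, on a scale that no header explains and with a ceiling that differs between lists. Scores were therefore used within a list or as ranks, and never compared as values between lists. The score is the authors' own value for a peak. The peak names end in a number from 1 to the size of the list, each used once, which follows the score. The replicate 2 list holds exactly 30000 peaks. Intervals entered more than once were kept as deposited.

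Overlap was at least 1 bp shared, counting 1-based inclusive ends. Chance overlap was measured by rotating the replicate 2 peaks by a random distance within each chromosome, 1000 times, which keeps their number, widths and clustering. The overlaps of both lists were counted from the same rotations. Overlap by peak number used 200 rotations of the other list, replicate 2 for replicate 1 peaks and replicate 1 for replicate 2 peaks. Distances between midpoints were compared with those after 200 rotations of replicate 2. The rank agreement between replicates was Spearman's rho over peaks with exactly 1 partner each way, with 100000 permutations. Ranks of shared and unshared peaks were compared with a permutation test of the mean rank, with 100000 resamples. Peaks on X were tested with an exact binomial test against the share of X in the chromosome span, and windows of 100 kb with permutation tests of the mean, using 100000 resamples for the combined list and 10000 for the replicate lists. Since no chromosome lengths of WS220 were used, the span of a chromosome was taken from the first to the last peak of any list. Intervals of shares are 95% exact (Clopper-Pearson) binomial intervals, densities have exact Poisson intervals, and a share of 0 is given with the limit of 3 counts. All of these cover counting error only. Adjusted p-values are Benjamini-Hochberg values over the 6 chromosomes. The comparisons were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.

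Parts of the calculations were tested on simulated data first. In a simulated list of replicate 2 size, a planted overlap of 10% of replicate 1 peaks was recovered as 9.80% and one of 30% as 28.7%, and with no planted overlap the estimate was 0.14% (permutation p = 0.28). These overlap estimates came from the surplus over rotation, a value not used for the overlaps reported below. For X, a single random count of peaks was drawn for the size of the combined list. With odds of 0.5 on X, the odds were recovered as 0.47, and with odds of 1 as 0.93 (exact binomial p = 0.11). A planted shift of 2000 ranks in a list of replicate 1 size was recovered as 1857, and with no shift the difference was 22.2 (permutation p = 0.79).

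The comparisons of overlap, rank agreement, combined against replicate lists, unshared peaks and X against the autosomes were set before the data were examined. The use of the peak number and of the covered span, the classes by rank or score, the tests of single chromosomes and of X against V, the window counts, the merging of peaks the rotated midpoint distances and the closing tests of position, spacing and weak peaks were chosen afterwards. Other settings were 50% reciprocal overlap, the higher scoring 50% of a list, and the top 3195 peaks of a single replicate in place of the combined list. The higher scoring 50% was taken by peak number because the score has a ceiling. Genes to be named were to be those with a promoter at the 12 highest scoring peaks or in 14 preset gene lists, and regions are named in their place. Promoter, motif, gene list, noncoding RNA and transgene locus comparisons had been planned on condition of a genome or annotation of the files' build. The gene table at hand is of assembly WBcel235, so it was not used with these coordinates, and those comparisons are not analysed here. The share of X among genes was left out for the same reason.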

Results

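Binding of the transcription factor DPL-1 was mapped in fed first-stage (L1) larvae of *Caenorhabditis elegans* by chromatin immunoprecipitation followed by sequencing (ChIP-seq). DPL-1 is the worm member of the DP family, the proteins that pair with E2F factors to bind DNA at genes of the cell cycle. The hermaphrodite strain YL448 carried a transgene in which the promoter of *ges-1*, an intestinal esterase gene, drove DPL-1 fused to GFP and a Flag tag, and chromatin was collected with antibodies against GFP. The peaks therefore concern DPL-1 made under an intestinal promoter, and binding of the native protein across the larva was not mapped. The study comprised 2 ChIP libraries and their 2 input libraries of total chromatin DNA. The peak lists of ChIP replicates 1 and 2 and a list of both combined were examined. The input libraries were not analysed here. Read counts are not given in the lists, so the sequencing depth behind each peak is unknown, and every interval below covers the counting of peaks only. The labels do not say whether the replicates came from separate cultures, so agreement between them may include technical replication only.

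The lists described many short intervals spread over the 6 nuclear chromosomes, in coordinates of WormBase build WS220. The replicate 1 list held 24366 peaks that covered 8.14% of the 100.2 Mb spanned by peaks, and the replicate 2 list held 30000 peaks that covered 8.40%. The combined list was far smaller, with 3195 peaks that covered 0.935% of the span. Most peaks had a single width, which was 344 bp for 97.3% of peaks in replicate 1, 284 bp for 98.2% in replicate 2 and 324 bp for 74.5% in the combined list. The authors' score had a ceiling that 2119 peaks reached in replicate 1, 2615 in replicate 2 and 2539 in the combined list. The authors also numbered the peaks, and the number rose as the score fell (Spearman rho = -0.9996 across peaks in replicate 1 and -0.9995 in replicate 2). In the combined list rho was -0.705, because 79.5% of its peaks share the ceiling, and the order among these rests on the authors' number alone. Number 1 was taken as the strongest peak of each list, and the numbers were used to order peaks that share the ceiling.

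The first comparison asked which peak regions recurred between the replicates. At 1 bp of overlap nearly all of the strong regions recurred. Of the 1000 strongest peaks of replicate 1, 99.9% (95% exact binomial interval 99.4 to 100.0) overlapped a replicate 2 peak by at least 1 bp, and all 1000 of the strongest replicate 2 peaks overlapped a replicate 1 peak (interval 99.6 to 100.0). With 50% reciprocal overlap, 136 of the 1000 strongest peaks of replicate 1 and 113 of replicate 2 were unmatched. The weak regions mostly did not recur. Among peaks numbered above 20000, 25.38% (24.09 to 26.70) of replicate 1 peaks and 20.9% (20.1 to 21.7) of replicate 2 peaks were matched, against means of 18.2% and 14.7% after the other list had been rotated along each chromosome. Across whole lists, 10059 replicate 1 peaks (41.3%, interval 40.7 to 41.9) overlapped replicate 2, which was 2.27 times the mean of 18.2% over 1000 rotations. In the other direction 33.05% (32.5 to 33.6) of replicate 2 peaks were matched, against 14.7% after rotation. In both directions the one-sided permutation p was 0.001, the smallest that 1000 rotations can give. No ChIP library from an untagged strain was among the samples, and the input libraries were not analysed. Recurrence, of strong peaks too, therefore does not separate DPL-1 binding from other signal shared by both libraries.

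**Figure D1:**
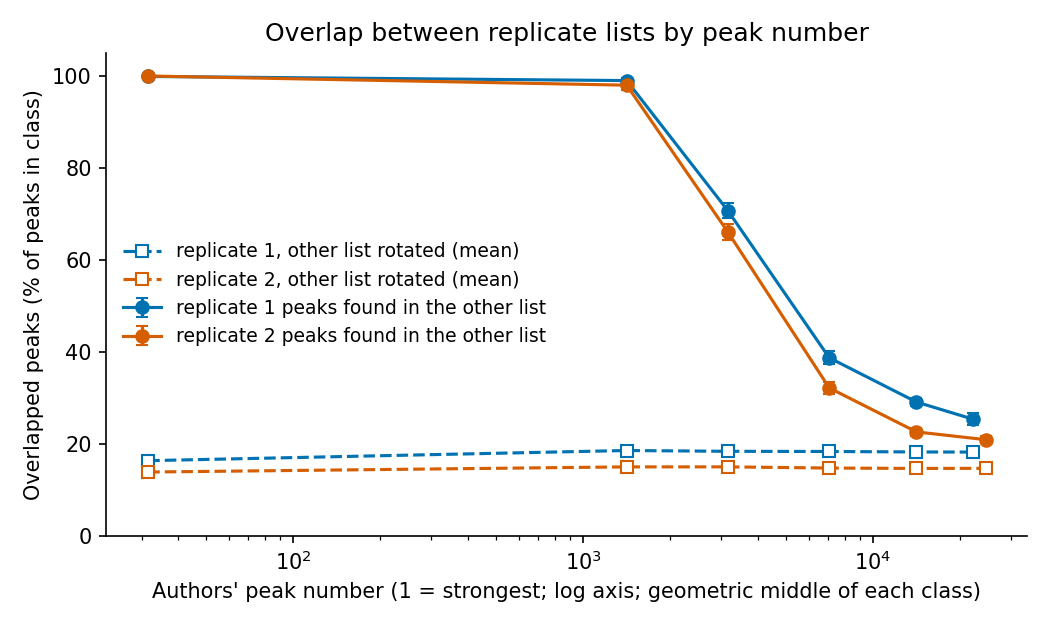
Percentage of peaks in each class of authors' peak number that overlap the other replicate's list by at least 1 bp (filled points, with 95% exact binomial intervals), and the mean after rotating the other list (open squares, 200 rotations). The horizontal log axis runs from the strongest peaks on the left to the weakest on the right. Matching falls from 99.9% for numbers 1 to 1000 of replicate 1 to 25.38% for numbers above 20000, where the rotated mean is 18.2%.

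The scores of matched peaks were correlated between the replicates. Over 8661 peaks that matched one to one, the scores of the 2 lists had a Spearman rho of 0.68 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). This correlation is across peaks, which are not independent replicates. It differed by the class of region. For the 2767 pairs lying on a combined peak, rho was 0.40 by score, where most peaks share the ceiling, and 0.85 by peak number. For the 5891 pairs on no combined peak it was 0.18. The combined list comes from the same libraries, so this division is not independent of the agreement measured, and part of the pairs outside it match by chance, since 18.2% of replicate 1 peaks overlapped replicate 2 after rotation. Midpoints of paired peaks lay a median of 18 bp apart on combined peaks and 98 bp apart elsewhere, and the 834 pairs among the 1000 strongest peaks of both lists lay a median of 9.5 bp apart. Pairs formed after rotating replicate 2 had medians of 132 to 160 bp over 200 rotations, with a mean of 153 bp, since pairing by overlap alone limits the distance. Of the 1000 strongest replicate 1 peaks, 872 (87.2%, interval 85.0 to 89.2) matched one of the 1000 strongest replicate 2 peaks. Of the 100 strongest, 82 (82%, interval 73.05 to 88.97) matched one of the 100 strongest.

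Regions found in 1 replicate list only were chiefly weak. The 14307 peaks found in replicate 1 only had a mean score rank of 14395 ± 5972 (SD) in their list, and the 10059 shared peaks had 9038 ± 7225. In replicate 2 the 20086 unshared peaks had a mean rank of 17129 ± 7591 and the 9914 shared peaks 10689 ± 9072. Both differences gave a two-sided permutation p of 1e-05, the smallest possible. Of the unshared peaks, 13 in replicate 1 and 70 in replicate 2 reached the score ceiling, and 180 and 265 did with 50% reciprocal overlap. At 1 bp the strongest unshared peak was number 923 in replicate 1, at chromosome II positions 11534568 to 11534911. In replicate 2 it was number 1204, at chromosome II positions 13195219 to 13195502.

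Nearly every combined peak was found in both replicate lists. Of the combined list's 3195 peaks, 3182 (99.6%, interval 99.3 to 99.8) overlapped a replicate 1 peak and 3171 (99.2%, interval 98.9 to 99.5) a replicate 2 peak, and 3158 overlapped both. The 37 combined peaks missing from 1 of the lists were numbered 1825 or higher, and none was missing from both. The median combined peak corresponded to number 1576 in replicate 1 and number 1572 in replicate 2. The combined list comes from the same libraries as the replicate lists, so no test was made of this overlap.

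The 12 strongest combined peaks ranked high in both replicates. They had numbers of 23 or better in replicate 1 and of 17 or better in replicate 2. The combined list comes from the same libraries, so its order is not independent of these numbers. Chromosome III held 3 of the 12 peaks. Number 1 lay at positions 3867354 to 3867747 of chromosome III and was number 1 in replicate 1 and number 2 in replicate 2. Number 2 lay at 7854440 to 7854784 and number 4 at 10758963 to 10759343 of the same chromosome. Chromosome II also held 3, with number 3 at 10563337 to 10563700, number 7 at 216623 to 216939 and number 8 at 4999169 to 4999501. Chromosome IV held number 5 at 14464043 to 14464401, number 11 at 12724638 to 12724968 and number 12 at 17249706 to 17250026. Chromosome V held number 6 at 10897203 to 10897546 and number 9 at 16965666 to 16965988. Chromosome I held number 10 at 12966736 to 12967105. No peak on X was among these 12. The strongest X peak was number 152, at positions 6804912 to 6805154, and it was number 152 in replicate 1 and number 158 in replicate 2. These regions were chosen by the authors' peak number after the score ceiling had been seen. No gene is assigned to them, because no annotation of build WS220 was used here. Reads from the *ges-1*, *dpl-1* and *unc-119* sequence of the transgene would map to those loci. Whether any region named here lies at such a locus was not examined.

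One region stood apart by its width. An interval of 2632 bp on chromosome III, positions 7814284 to 7816915, was entered 3 times in the combined list, as numbers 1029, 1232 and 2380. The same place appeared as an interval of 2607 bp entered 2 times in replicate 1 and as one of 2602 bp entered 4 times in replicate 2. The next widest peak was 590 bp in the combined list, 450 bp in replicate 1 and 320 bp in replicate 2.

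**Figure D2:**
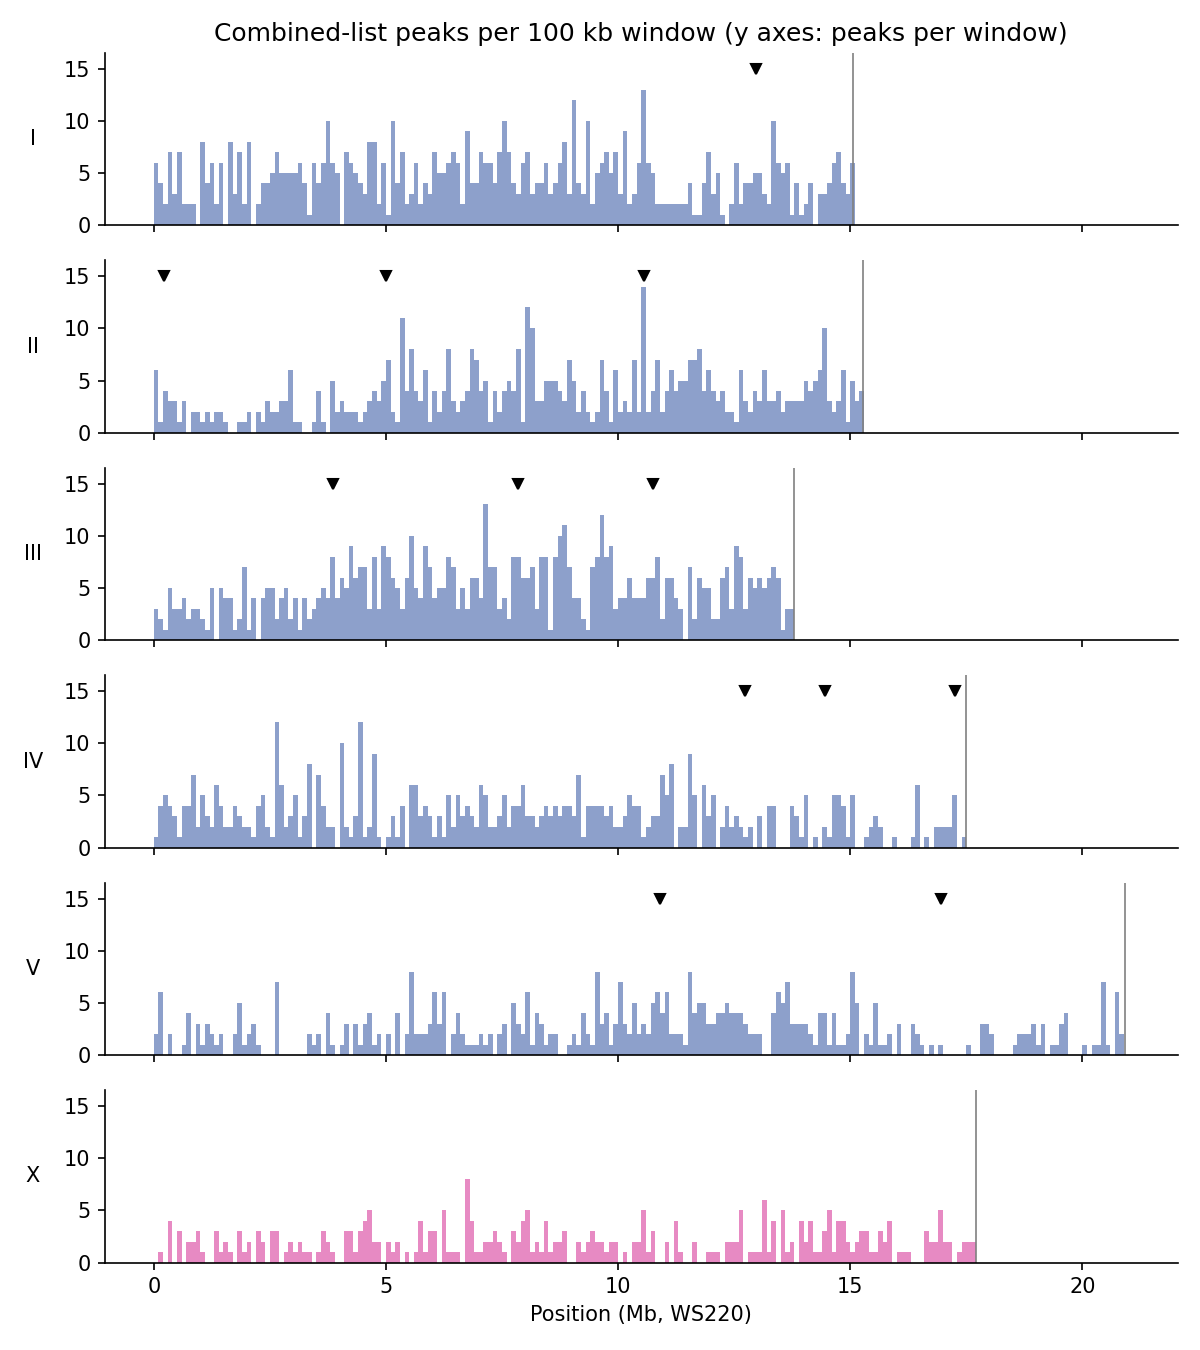
Number of combined-list peaks in each 100 kb window (vertical axis) along the 6 chromosomes (horizontal axis, Mb in build WS220), with the 12 strongest peaks as black triangles and the last peak of any list as a grey line. The highest window, with 14 peaks, lies on chromosome II, and no window on X holds more than 8 peaks.

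Peaks were spread unequally over the chromosomes. X, which hermaphrodites carry in the same copy number as the autosomes, had the fewest peaks per Mb in the combined list. In the replicate lists V was lowest, with 211 peaks per Mb (205 to 218) against 214 (208 to 221) on X in replicate 1, and 272 (265 to 280) against 281 (274 to 289) in replicate 2. The combined list placed 311 peaks on X, or 17.6 per Mb (95% exact Poisson interval 15.7 to 19.6), and 2884 peaks on the 5 autosomes, or 35.0 per Mb (33.7 to 36.3). X thus held 9.73% of the peaks (interval 8.73 to 10.8) and 17.7% of the span covered by peaks (two-sided exact binomial p = 1.6e-36). Chromosomes III and I had the highest densities, with 49.2 (45.6 to 53.04) and 45.8 (42.4 to 49.3) peaks per Mb. Chromosome II had 35.7 (32.8 to 38.8) and chromosome IV 29.8 (27.3 to 32.5). Chromosome V had 21.6 (19.6 to 23.6), which was the lowest value among the autosomes. Because neighbouring peaks are not independent, peaks were also counted in 100 kb windows, and the windows were permuted as if independent. The 177 windows on X held 1.76 ± 1.49 (SD) peaks and the 822 autosomal windows 3.49 ± 2.55, a difference with a two-sided permutation p of 1e-05, the smallest possible. When the windows of each chromosome were compared with all others, Benjamini-Hochberg adjusted permutation p was 1.5e-05 for the excess on I and III and for the deficit on V and X. It was 0.052 for II and 0.25 for IV, so neither passed the threshold. The excess on II did pass the exact binomial test, which treats peaks as independent (adjusted p = 0.0060). Chromosome IV had an excess by windows in replicate 1 (adjusted permutation p = 0.0044) and did not pass in replicate 2 (adjusted p = 0.38). In the combined list X also lay below V, at 0.81 times its density (exact binomial p = 0.0057, window permutation p = 0.030).

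**Figure D3:**
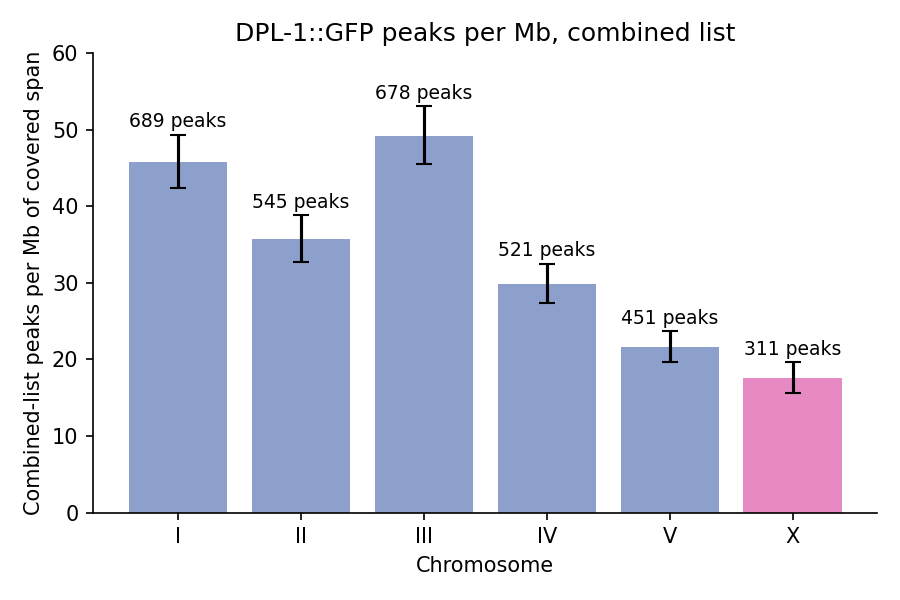
Combined-list peaks per Mb of span covered by peaks (bars, from 0) for each chromosome, with 95% exact Poisson intervals and the number of peaks above each bar. X has 17.6 peaks per Mb, and chromosomes III and I have 49.2 and 45.8.

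The deficit on X was deepest among strong regions and was not detectable among the weaker 50% of either replicate list. Of the 1000 strongest combined peaks, 39 (3.90%, interval 2.79 to 5.29) lay on X. The share was 11.5% (9.59 to 13.6) for numbers 1001 to 2000 and 13.1% (11.3 to 15.2) for numbers 2001 to 3195. None of the 100 strongest lay on X, which allows a share of up to 3% by the limit of 3 counts and up to 3.62% by the exact binomial interval. Each replicate gave the same gradient. The 1000 strongest peaks had 3.60% (2.53 to 4.95) on X in replicate 1 and 3.70% (2.62 to 5.06) in replicate 2. Whole replicate lists had 15.6% (15.1 to 16.0) and 16.6% (16.19 to 17.04) on X. Their weaker 50% had 17.2% (16.6 to 17.9) and 17.5% (16.9 to 18.2), and the share of X in the span was 17.7%. Many of these weak peaks may be background, since 27.3% of those in replicate 1 overlapped replicate 2, against 18.2% after rotation. Background calls spread over the span would fall on X near its share, so an even spread of weak binding is not shown. Within the combined list, peaks on X had a mean number of 1985 and the others 1556 (two-sided permutation p = 1e-05, adjusted p = 6e-05 over the 6 chromosomes). Peaks on chromosome III had lower numbers than the others, with a mean of 1493 against 1626 (two-sided permutation test, adjusted p = 0.003), and chromosomes I, II, IV and V did not pass the threshold in the combined list. In both replicate lists I, III, V and X passed (permutation test, adjusted p = 0.00015 for each). Peaks on I and III were stronger than the others there, and peaks on V and X weaker. These tests of peak number treat single peaks as independent, which neighbouring peaks are not. Among the 1000 strongest combined peaks, X had 2.203 per Mb and V 7.55 per Mb (exact binomial p = 2.7e-14). In the weaker 50% of the combined list X had 11.9 per Mb and V 10.5 per Mb, a difference that did not pass (exact binomial p = 0.21). The division by rank was made after the counts per chromosome had been seen. Taken by score alone, X held 8.70% (7.64 to 9.87) of combined peaks at the ceiling and 13.7% (11.2 to 16.6) of those below it.

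**Figure D4:**
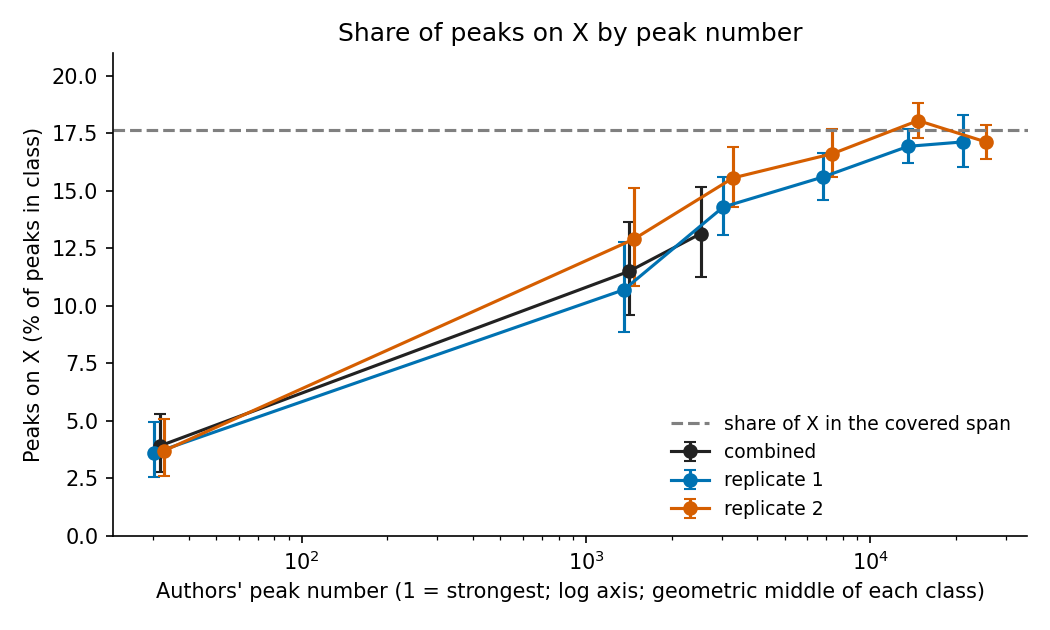
Percentage of peaks that lie on X in each class of authors' peak number (log axis, strongest on the left) for the combined list and both replicate lists, with 95% exact binomial intervals. The dashed line is the share of X in the span covered by peaks, 17.7%, and the share on X climbs from 3.90% of the 1000 strongest combined peaks to 17.1% of the weakest class of each replicate.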

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

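The tests with merged peaks, permuted windows, chromosome V, expectations from weak peaks, peak numbers and pairs on no combined peak were chosen after the data had been seen, as was reciprocal overlap for unshared peaks. No paired analysis was possible because the input libraries that share replicate numbers with the ChIP libraries were not analysed here. All 18 alternatives to the tested results (overlap, rank agreement, ranks of unshared peaks and the share on X) kept the direction and stayed past the threshold. Those for X used the combined list or the top 3195 peaks of a replicate. The weaker 50% of each replicate list, where no deficit on X was detectable, was not among them. The overlap of replicate 1 peaks ranged from 30.04% with 50% reciprocal overlap to 78.3% among the top 3195 peaks of each list, and the share on X ranged from 6.32% in the stronger 50% of the combined list to 10.6% without replicate 1 (9.23% without replicate 2). The rank agreement ranged from 0.18 for pairs on no combined peak to 0.85 for pairs on a combined peak ordered by peak number, and was 0.74 with reciprocal overlap. The 6 alternatives for the share of combined peaks found in a replicate list moved it. With 50% reciprocal overlap it was 93.9% in replicate 1 and 91.1% in replicate 2, with the top 3195 peaks of each replicate it was 89.3% and 87.1%, and with the stronger 50% of every list it was 100.0% in both. The lower values follow from demanding more overlap or from fewer replicate peaks. The combined peaks missing from a list are numbered 1825 or higher, so none of them is in the stronger 50%. The overlap between replicates cannot be computed with 1 replicate left out. The settings intended for promoters, motifs, gene lists and noncoding RNA genes, and the share of X among genes, were not run. The lists give no read depth, so a region absent from a list is not shown to be unbound.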

Other observations

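The tests of position, spacing, detection and windows here were chosen only after counts along and between the chromosomes had been seen, as was the criterion for shoulders of combined peaks, while the test of regional density was set after the overlap by rank had been seen but before the value that decides it. Peaks on the autosomes were denser towards the middles of the chromosomes. In the combined list 59.4% (95% exact binomial interval 57.6 to 61.2) of autosomal peaks lay in the central 50% of the span, from 25% to 75% of its length. The excess was largest on chromosome V, with 68.1% (63.5 to 72.4), and chromosome III had 60.6% (56.8 to 64.3), chromosome II 58.3% (54.1 to 62.5) and chromosome I 56.0% (52.2 to 59.8). By 100 kb windows these passed with adjusted permutation p of 6e-05, 6e-05, 0.0016 and 0.011, over the 6 chromosomes. Chromosome IV, with 55.9% (51.5 to 60.2), did not pass the permutation test (adjusted p = 0.052), nor did X, with 51.4% (45.7 to 57.1, adjusted p = 0.73). The lists differed on these chromosomes. X passed in the replicate 1 list, with 52.95% (adjusted permutation p = 0.015), and not in replicate 2 (adjusted p = 0.13). IV passed in replicate 2, with 52.6% (adjusted permutation p = 0.0036), and had 49.8% in replicate 1 (adjusted p = 0.79). Among the 1000 strongest combined peaks III and V alone passed the permutation test (adjusted p = 0.010 and 0.0012), and IV had 50%. The difference between X and the autosomes in this respect was not tested.

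Combined regions also lay closer together than uniform placement gives. After merging, 3162 regions had a median distance between neighbouring midpoints of 17332 bp, against a median of 20203 bp, averaged over 1000 random placements on each chromosome. Neighbours under 2 kb apart made up 10.6% of distances, 1.54 times the random mean of 6.87% (permutation p = 0.001, the smallest that 1000 placements can give). Uniform placement ignores the denser middles of the autosomes, so local clustering beyond that gradient is not shown. The densest 100 kb windows held 14 combined peaks on chromosome II (10500001 to 10600000), 13 on chromosome I (10500001 to 10600000) and 13 on chromosome III (7100001 to 7200000). The longest stretch without a combined peak was 621 kb on chromosome V, positions 2694754 to 3315309. It held 111 replicate 1 peaks, or 179 per Mb against 211 on the whole of V. It held 130 replicate 2 peaks, or 209 per Mb against 272. Because the stretch was chosen for its lack of combined peaks, replicate peaks that overlap them are missing from it by selection. Counting only replicate peaks on no combined peak, V had 188 per Mb in replicate 1 and 250 in replicate 2. The stretch also lies in the outer part of V, where windows held fewer peaks than central ones in both replicate lists. Whether it is sparser than its surroundings was not tested.

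X held few strong peaks and close to its span share of weak ones. Clustering of peaks within a window, with peaks counted as independent, is argued against by the window permutation p of 1e-05. That test treats the windows themselves as independent, so it cannot decide on clustering over distances longer than a window. Lower detection across X cannot be told apart. Whole replicate lists had 15.6% (15.1 to 16.0) and 16.6% on X, below the span share of 17.7% but by less than the combined list. The share among weak peaks decides nothing, since lower detection would itself move peaks on X to weaker ranks. Background calls among the weak peaks would also fall on X near its span share. A difference in the number or kind of genes on X, or in chromatin that the input libraries would show, also stays open and may account for the pattern. Neither was tested, because no annotation of build WS220 was used and the input libraries were not analysed. No other biological explanation was tested, and the study has a single strain and stage, with the mapped DPL-1 made from a transgene.

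Weak peaks of replicate 1 recurred in replicate 2 above rotated positions. In the weaker 50% of replicate 1, 27.3% overlapped replicate 2 against a rotated mean of 18.2% (permutation p = 0.001). Regional density of peaks would keep this surplus when each peak is moved by 2 to 10 kb, but only 10.5% of it was kept. Shoulders of combined peaks would remove the surplus when weak peaks within 1 kb of a combined peak are left out. Among the 11358 peaks that remained, the surplus was 8.23 percentage points. That was 90.1% of the 9.13 points among all 12183 weak peaks. The criterion for shoulders was made stricter after this value had been seen, with the same outcome. A candidate explanation that stays open is weak binding or a local bias shared by both libraries, such as accessible chromatin, which cannot be separated without the input libraries.

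The central excess on autosomes may come in part or whole from lower detection in the outer 25% at each end, which cannot be told apart. Whole replicate lists had 55.3% (54.7 to 55.9) of autosomal peaks in the central 50% in replicate 2 and 53.5% in replicate 1, an excess in the same direction as the 59.4% of the combined list and smaller. Shares among weak peaks decide nothing here either, because rank depends on detection. Clustering of peaks within a window is argued against by the window permutation p of 1e-05 for the autosomes. Clustering over distances longer than a window cannot be decided, because the test treats windows as independent. Gene density, which was not analysed here, also stays open.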
